A study of Mus musculus with 24 samples.

How the data were processed

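Messenger RNA was sequenced from mouse colon in 24 libraries of C57Bl/6 mice. The samples were either whole colon wall, 10 mm pieces cut about 10 to 20 mm from the rectum, or colon epithelial cells, per the labels' protocols. The mice were either VilCre controls, which carry a Cre recombinase active in gut epithelium, or VilCre mice that also carry a caNrf2 transgene, an active form of the transcription factor NRF2, which the gene Nfe2l2 encodes. Colon wall came from mice with or without dextran sulfate sodium (DSS), a chemical that damages the colon lining of mice. The labels give 6 groups of 4 libraries: control and transgenic epithelial cells without DSS, and control and transgenic colon wall, each untreated or with DSS. The series text speaks of 3 replicates per condition, and 4 libraries per group were used here. Nothing in the labels says that replicates of a group were separate animals, so the p-values measure only the spread between these samples, part of which may be technical. The dose and duration of DSS, the time of day of sampling and the way epithelial cells were separated are not given in the sources used here.

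Per the file headers, each deposited file holds, for 30383 RefSeq transcripts, an estimated read count (an expected count, not divided by length or depth), a posterior estimate of that count, TPM and FPKM values, and further expression values whose scale the header does not give. The authors' estimated counts were the values used for the tests: 39.2% of them were not whole numbers, which is the form that programs such as RSEM give. RSEM 1.2.11, FastQC and the mouse genome build mm10 are listed in the submitters' processing notes, without role or order. The authors' TPM and FPKM values per transcript and the deposited expression score columns were not used in any test. The aligner, the strand setting, read filters and the RefSeq release are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart, and closely related genes such as Gsta1 and Gsta2 may share reads. Whether transgene transcripts were counted under Nfe2l2 is not given in the sources used here.

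The deposited expected counts were summed over the transcripts of each gene symbol, giving 23329 symbols, and rounded to whole numbers. Library totals ran from 20232317 to 154335999 counts in colon wall and from 6683785 to 15399870 in epithelial cells. CPM values are counts scaled by edgeR to the TMM-scaled library size. Of all 36 pairs of libraries within a group, none had counts within sampling noise of each other (lowest chi-square per gene 10.2, over genes with at least 20 counts in both), so each library was counted as 1 replicate. Gene positions are those of the deposited files on mm10, written 1-based.

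The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment, and an adjusted p below 0.05 as the threshold. The 8 epithelial libraries were fitted alone, with 12941 genes tested and a common biological coefficient of variation of 0.36. The 16 colon wall libraries were fitted together, with 16074 genes and a coefficient of 0.26. The difference between the tissues used the 8 epithelial and the 8 untreated colon wall libraries, with 15073 genes and a coefficient of 0.30. The 7 comparisons were the transgene effect in epithelial cells, in untreated colon wall and in DSS-treated colon wall, the DSS effect in each genotype, the difference of the DSS effect between genotypes, and the difference of the transgene effect between epithelial cells and untreated colon wall. Log2 fold changes are given with a standard error (SE) derived from the test, the absolute log2 fold change divided by the square root of its F statistic. Group values are given as mean CPM with the SD and 4 libraries per group.

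The steps were tested on simulated counts drawn from the means and library sizes of the real samples. Each gene was drawn independently with its fitted spread, without a batch, odd libraries or a DSS effect on the unchanged genes. The shares below come from a single draw per comparison. They hold for such counts and are not error rates of the real tests. Of genes changed 2-fold, 25.3% were recovered in the epithelial comparison (12741 genes) and 55.6% in the untreated colon wall comparison (16032 genes). Of genes changed 4-fold, 75.5% and 90.0% were recovered in these comparisons. In the difference of the DSS effect between genotypes (16033 genes), 7.1% and 75.0% were recovered at these fold sizes, and 13.1% and 57.0% in the difference between the tissues (14950 genes). False calls made up 6.6% of the simulated calls in epithelial cells, 3.3% in untreated wall and 1.4% for genotype with DSS. They made up 5.5% for DSS in controls, 7.6% for DSS in transgenic wall, and 4.7% and 4.1% for the differences between genotypes and tissues.

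The design, the tests, 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists hold 528 entries, of which 525 were matched to symbols of the files, 11 of them through an older symbol. For each list, members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation and fry, adjusted over the lists of a comparison. Camera compares a list with the other genes. The directional fry test asks whether a list's genes move, on balance, one way, and its mixed test whether they change in either direction. Several members are held in common by more than 1 list, and the marker lists of other cell types contain genes that epithelium also expresses. A list score is the mean of log2(CPM + 1) over its members. The overlap of calls between comparisons was tested with Fisher's exact test.

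Named genes were Nfe2l2 and, per comparison, up to 8 genes higher and 8 lower with the largest fold change among genes past the threshold. These needed a mean of at least 5 CPM, no overlap between the groups compared and a symbol that is not a predicted or clone name. From each list came up to 4 members past the threshold with the smallest p, or 1 where none passed. From those that met the rule, a selection is given, and some are not reported here. Genes named in one comparison were also given in others. Arntl, Npas2, Trib3, Chac1, Hmox1, Ciart (listed as Gm129), Nr1d2, Per1, Blvrb, Jund, Krt5, Lor, Ccl2, Acox2, Il1f9, Serpinb11, Slc5a4b, Sprr2g, H60c, Rn45s, Hoxb8 and Hoxb13 were named outside the rule where they appear so, after their values were seen. Old symbols were kept as in the files.

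Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, each library left out in turn, and a fit of only the 2 groups compared. The deposited file names begin with 1 of 2 numbers, which sets the replicate 4 libraries of the colon wall apart from the others. This was treated as a batch, once as a term and once by leaving those 4 libraries out. The 4 epithelial libraries that share a file-name number with a colon wall library were left out once, since they may come from the same animals. A fit without both control 3 and transgenic 1 epithelial libraries, a term for the endothelial score and a robust quasi-likelihood fit were chosen after seeing the data. All 35 splits of 4 against 4 libraries, or 100 drawn splits for the differences of effects, were refitted.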

Results

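Messenger RNA was counted in 24 mouse colon libraries, 4 in each of 6 groups. The groups were epithelial cells of control and caNrf2 transgenic mice, and colon wall of both genotypes, either untreated or after DSS, a chemical that damages the colon lining. The series title names the question: how the transgene, DSS and both together change expression in the colon wall and in the epithelium. Total counts ran from 6683785 to 14291465 in control and from 7736498 to 15399870 in transgenic epithelial cells. In untreated colon wall they ran from 22823662 to 105029745 in controls and from 21493139 to 154335999 in transgenic mice. With DSS they ran from 20232317 to 44483251 in controls and from 27500284 to 43318925 in transgenic mice.

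Nfe2l2, the gene that encodes NRF2 (chromosome 2, 75675519 to 75704641, minus strand), was measured first in every library as a check of the labels. In epithelial cells it was at 138.8, 160.2, 203.2 and 168.8 CPM in the control libraries and at 370.1, 343.6, 291.6 and 231.0 CPM in the transgenic ones. In untreated colon wall it was at 99.5, 129.7, 120.9 and 146.2 CPM in controls and at 189.7, 147.6, 201.8 and 238.5 CPM in the transgenic libraries. With DSS it was at 147.9, 125.8, 110.6 and 167.9 CPM in controls and at 185.6, 166.4, 284.7 and 211.2 CPM in the transgenic libraries. The library labelled untreated transgenic replicate 2 thus lay at the upper edge of the control range, and its glutathione list score of 6.13 was below the highest control score of 6.18, while the other 3 transgenic libraries scored 6.97 or more. It was kept in its group, and every direction given for untreated transgenic colon wall draws on it. The fitted Nfe2l2 difference between genotypes was a log2 fold change of 0.88 ± 0.18 (SE) in epithelial cells, 0.65 ± 0.19 in untreated wall and 0.62 ± 0.19 in DSS-treated wall. None passed the threshold in edgeR's test (adjusted p = 0.219, 0.199 and 0.957).

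**Figure D1:**
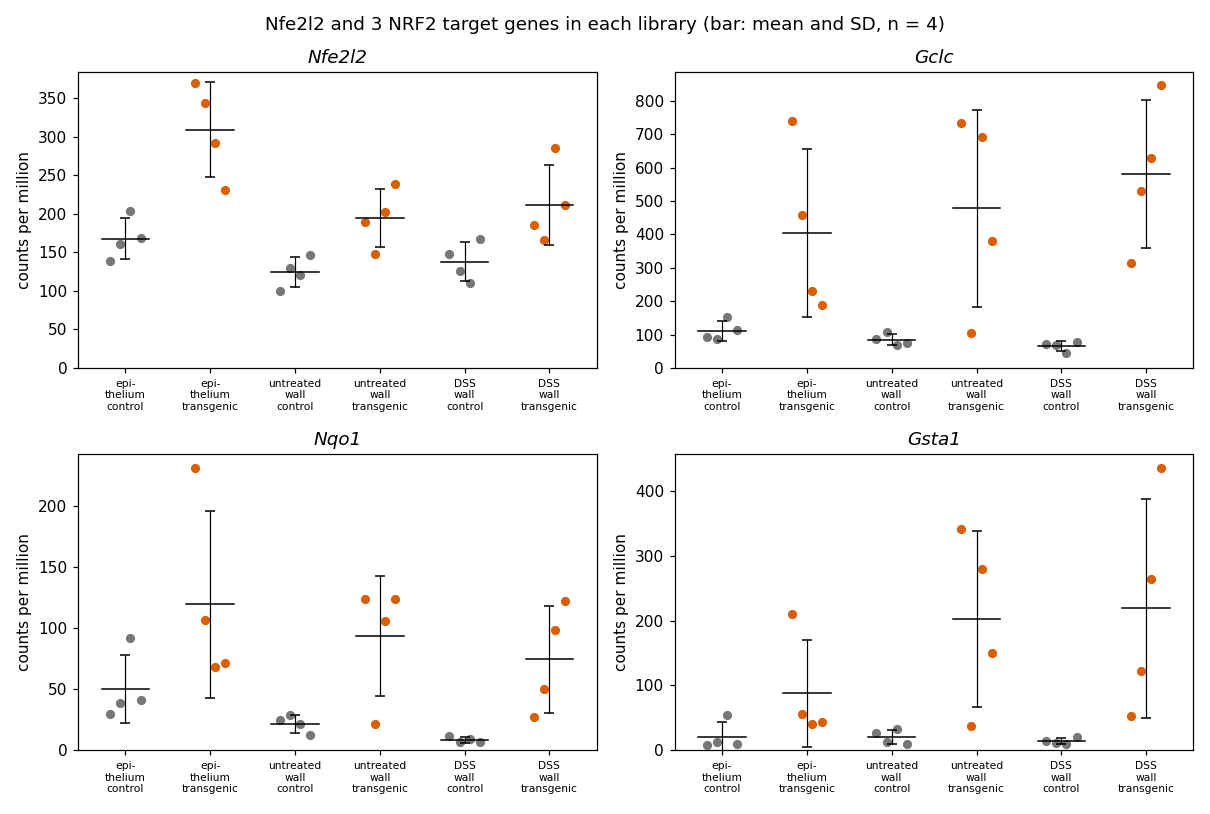
CPM (vertical axes) of Nfe2l2 and of Gclc, Nqo1 and Gsta1 in each library of the 6 groups (horizontal axes), with the mean and SD of 4 libraries as bars. Nfe2l2 was at 231 to 370.1 CPM in transgenic and 138.8 to 203.2 CPM in control epithelial cells, and Gclc was at 314.7 to 847 CPM in transgenic and 44.6 to 77.2 CPM in control colon wall with DSS.

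In epithelial cells without DSS, no gene passed the threshold between genotypes over all genes. Slc7a11, the cystine importer that feeds glutathione synthesis, was at 36.1 ± 13.6 CPM (SD, n = 4) in transgenic and 6.5 ± 3.61 CPM in control cells. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis (chromosome 9, 77754535 to 77794489), was at 404.5 ± 252.7 against 111.9 ± 29.4 CPM. Abcc4, an efflux pump, was at 66.1 ± 23.8 against 18.2 ± 4.75 CPM, with 11.1 CPM in control replicate 3, and Gsta3, a glutathione S-transferase, at 60.1 ± 25.2 against 16.5 ± 4.23 CPM. Mx1, an interferon-induced GTPase, was at 15.6 ± 3.47 CPM in transgenic and 74.3 ± 36.8 CPM in control cells. The log2 fold changes of these genes were 2.48 ± 0.53 (SE) for Slc7a11, 1.85 ± 0.42 for Gclc, 1.86 ± 0.31 for Abcc4, 1.87 ± 0.34 for Gsta3 and -2.25 ± 0.42 for Mx1. The edgeR test called 0 of 12941 genes, with a smallest adjusted p of 0.219, while 1344 genes had an unadjusted p below 0.05, where chance alone gives 647. DESeq2 called 215 genes and voom with quality weights 1292. Values of the 2 groups did not overlap for 939 genes, or 7.26%, where chance gives 2.86%.

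Among the lists in epithelial cells, all 23 measured genes of glutathione synthesis and conjugation had a fitted change above 0, with a median of 0.60, and 7 passed when adjusted over the list alone. All 14 quinone, thioredoxin, heme and iron antioxidant genes were fitted above 0 (median 0.82), and Cbr3, a carbonyl reductase, and Hmox1, heme oxygenase, passed over the list alone. Cbr3 was at 154.3 ± 89.2 against 33.7 ± 15.4 CPM, and Nqo1, a quinone reductase (chromosome 8, 107388225 to 107403205), was at 119.4 ± 76.6 against 50.3 ± 28 CPM without passing. All 6 NADPH-producing enzymes were fitted above 0 (median 0.51), and none passed over the list alone. Of 34 drug metabolism and efflux genes, 28 were fitted above 0 (median 0.33) and Abcc4 passed. Camera called these 4 lists higher (adjusted p = 1.02e-14, 1.1e-08, 0.000622 and 3e-05). The calls were lost with an estimated correlation (adjusted p = 0.684 for the first 3 and adjusted p = 0.994 for drug metabolism with an estimated correlation), and fry gave adjusted p = 0.396, 0.54, 0.396 and 0.991.

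Camera also called 2 lists lower in transgenic epithelial cells. Of 9 measured cytokines and chemokines the median was -0.76, and Nos2, inducible nitric oxide synthase, passed over the list alone with 2.09 ± 1.83 against 9.47 ± 3.55 CPM. This list had an adjusted p of 0.0127, and adjusted p = 0.684 with an estimated correlation. Of 15 genes of the unfolded protein and ATF4 response, 6 were lower and 1 higher over the list alone. Dnajb9, a chaperone of the endoplasmic reticulum, was at 21 ± 4.49 against 41.9 ± 8.85 CPM, and the higher one was Trib3, a target of ATF4. Chac1, another member, had a count of 0 in transgenic replicate 3 alone. This list also had an adjusted p of 0.0127, and adjusted p = 0.994 with an estimated correlation. The other 24 lists tested had no camera call.

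Circadian clock genes differed in both directions in epithelial cells, with 0 of 13 past the threshold over all genes in edgeR. Of the 13, 4 were higher over the list alone (Dbp, Per3, Tef and Ciart) and 5 lower (Arntl, Npas2, Nr1d1, Nr1d2 and Per1), and fry's mixed test gave an adjusted p of 0.00138. Tef, a transcription factor under clock control, was at 87.8 ± 9.99 CPM in transgenic and 48.1 ± 14.6 CPM in control cells, and Nr1d1, a repressor of the clock loop, at 166.1 ± 16.5 against 243.9 ± 16.7 CPM. Ccna2, a cyclin, was the member of the proliferation list with the smallest p, at 68.2 ± 9.45 against 97.8 ± 9.29 CPM, with 82.2 CPM in transgenic replicate 4, and did not pass over its list alone (adjusted p = 0.079, edgeR).

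Marker lists set control replicate 3 and transgenic replicate 1 apart from the other 6 epithelial libraries. Their absorptive colonocyte scores were 8.05 and 8.03, against 5.40 to 6.60 in the other 6, and their endothelial scores 1.01 and 1.08, against 2.70 to 3.66. Gsta1, a glutathione S-transferase, was at 54.4 CPM in that control library and at 210.4 CPM in that transgenic one, above the others of their groups. Transgenic replicate 1 also had the highest scores of all 8 libraries for the glutathione (7.66), quinone (8.77) and NADPH (8.48) lists, with at most 7.04, 7.94 and 8.09 in the 6 others. Leaving out control replicate 3 gave 24 genes past the threshold and leaving out transgenic replicate 1 gave 1. Without both, 835 genes passed, 45.6% of them higher, and with a term for the endothelial score 212 passed. Both of the last settings were chosen after seeing the data.

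**Figure D2:**
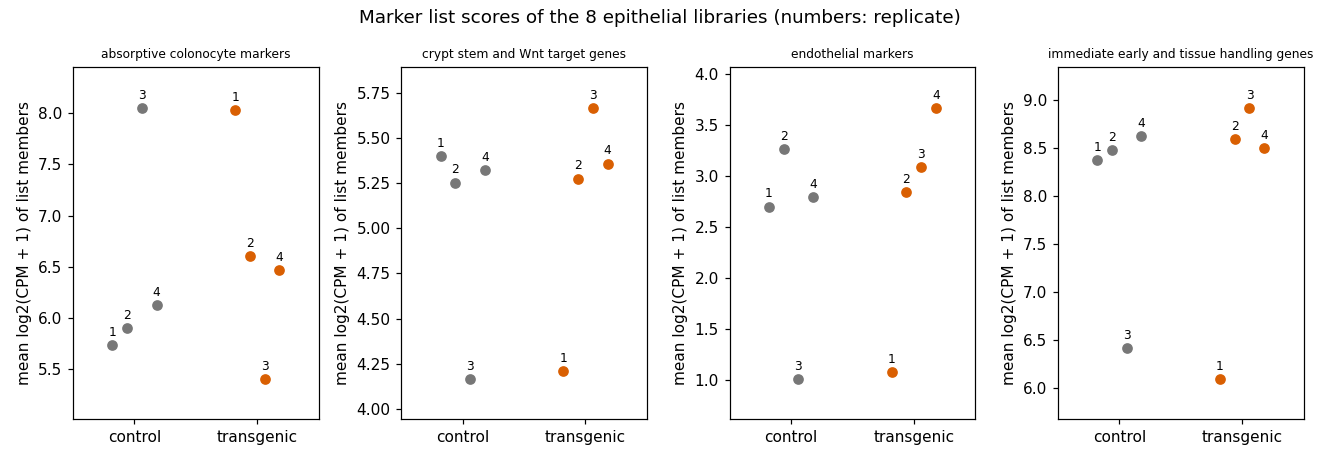
Mean log2(CPM + 1) over the members of 4 lists (vertical axes) in the 8 epithelial libraries by genotype (horizontal axes), with replicate numbers beside the points. Control 3 and transgenic 1 lie apart in all 4 panels, with colonocyte scores of 8.05 and 8.03 against at most 6.60 in the others.

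In untreated colon wall, 36 genes passed edgeR's test between genotypes, 22 higher and 14 lower in transgenic mice. The higher ones include members of the glutathione and drug metabolism lists. How far the calls rest on single libraries is given below. Abcc2, an efflux pump for glutathione conjugates (chromosome 19, 43782308 to 43838218), rose by 4.40 ± 0.62 log2 units (adjusted p = 0.00516), from 3.62 ± 0.62 to 75.7 ± 48.8 CPM. Gclc rose by 2.49 ± 0.44 and Slc7a11 by 2.67 ± 0.52 (adjusted p = 0.0344 and 0.0449). Gsta2, a glutathione S-transferase closely related to Gsta1, also passed (adjusted p = 0.0348), with 0.085 ± 0.063 CPM in controls and 10.1 ± 6.88 CPM in the transgenic group. The transgenic libraries 1, 3 and 4 held 343 to 786 counts of Gsta2, while the library labelled replicate 2 held 5, as many as 2 of the controls. Il7, a lymphocyte growth factor, rose by 1.19 ± 0.22, Dapp1, an adaptor of phosphoinositide signalling, by 1.19 ± 0.16, with 21.5 CPM in replicate 4 below the other transgenic libraries, and Sstr1, a somatostatin receptor, by 1.34 ± 0.18. Cyp4f39, a cytochrome P450, rose by 3.82 ± 0.72, and Ikbkg, the regulatory subunit of the IκB kinase, by 1.14 ± 0.22.

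Among genes that fell in untreated transgenic wall, Slc34a2, a sodium-phosphate transporter, fell by 2.26 ± 0.38 log2 units (adjusted p = 0.0221, edgeR), from 87.2 ± 35.7 to 18 ± 11.4 CPM. Rfx2, a transcription factor (chromosome 17, 56775897 to 56831008), fell by 1.94 ± 0.26 from 10.9 ± 1.31 to 2.85 ± 0.93 CPM. Nfatc2, a transcription factor of calcium signalling, fell by 1.27 ± 0.23, and Dusp10, a phosphatase of stress kinases, by 1.24 ± 0.23. Iffo2, of the intermediate filament family, fell by 0.65 ± 0.11. These directions include the library labelled transgenic replicate 2. Of the 36 genes, 28 were also tested in epithelial cells, and 22 of them had the same sign there, with 0 past the threshold.

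Of the lists in untreated wall, 3 of 24 glutathione genes passed over all genes and 7 when adjusted over the list alone, all higher (median 0.55). Of 37 drug metabolism and efflux genes, 1 passed over all genes and 8 over the list alone, all higher. None of the 14 quinone and thioredoxin genes passed over all genes, and Nqo1, Cbr3 and Blvrb passed over the list alone. Nqo1 was at 93.6 ± 48.9 against 21.8 ± 7.21 CPM. The 6 NADPH-producing enzymes were all fitted above 0, and none passed. Camera called the glutathione, drug, quinone and NADPH lists higher (adjusted p = 4.76e-10, 4.76e-10, 1.95e-05 and 0.0131), and the calls were lost with an estimated correlation (adjusted p = 0.64 for each with an estimated correlation).

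Camera called 3 more lists higher in untreated transgenic wall. Of 15 circadian clock genes, Dbp, Hlf, Per3 and Tef were higher and Arntl and Npas2 lower over the list alone, and 0 passed over all genes. Dbp, a transcription factor under clock control (chromosome 7, 45705247 to 45710203), was at 145.4 ± 72.5 against 26.6 ± 16.6 CPM, and Per3 at 55.6 ± 13.8 against 19.5 ± 3.45 CPM. Of 18 fatty acid oxidation genes, Pdk4, an inhibitor of glucose oxidation, passed over the list alone at 33.5 ± 22.6 against 9.86 ± 1.26 CPM. None of 18 monocyte and macrophage markers passed (median 0.36). These calls had adjusted p = 0.0131, 0.0348 and 0.0171 in camera, and adjusted p = 0.64, 0.883 and 0.883 with an estimated correlation.

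Lower in camera were the immediate early, cytokine and matrix lists. Of 15 immediate early and tissue handling genes, Hspa1a and Jund were lower over the list alone (median -0.82), with Hspa1a, a heat shock chaperone, at 17 ± 3.18 against 44.8 ± 20.2 CPM. Of 24 cytokines and chemokines, Ccl2 and Ccl7 were lower over the list alone, and of 18 matrix remodelling genes 0 passed. The adjusted p-values were 1.95e-05, 0.00187 and 0.0131, and adjusted p = 0.64, 0.883 and 0.883 with an estimated correlation. Outside camera's calls, Car1, a carbonic anhydrase of colonocytes, was higher over the colonocyte list alone, at 4099 ± 1495 against 1506 ± 700.2 CPM. Of 13 cornified envelope and squamous keratin genes, 2 (Krt5 and Lor) were higher and 5 lower over the list alone, among them Krt15, a keratin, at 0.75 ± 0.22 against 1.82 ± 0.98 CPM (fry's mixed test, adjusted p = 0.00641). Fry called none of the 32 lists in this comparison in its directional test.

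The count of 36 in untreated wall rested on single libraries and on the test. It was 6, 7, 5 and 320 without control replicate 1, 2, 3 or 4, and 9, 6 and 122 without transgenic replicate 1, 3 or 4. Leaving out the library labelled transgenic replicate 2 gave 41 genes, 25 of them among the 36. The 12 libraries of the first batch gave 404 genes, 34 of them among the 36, and the second batch holds 1 library per group. A batch term gave 19, the replicate block 7, a fit of only these groups 10, DESeq2 235 and voom 2491.

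**Figure D3:**
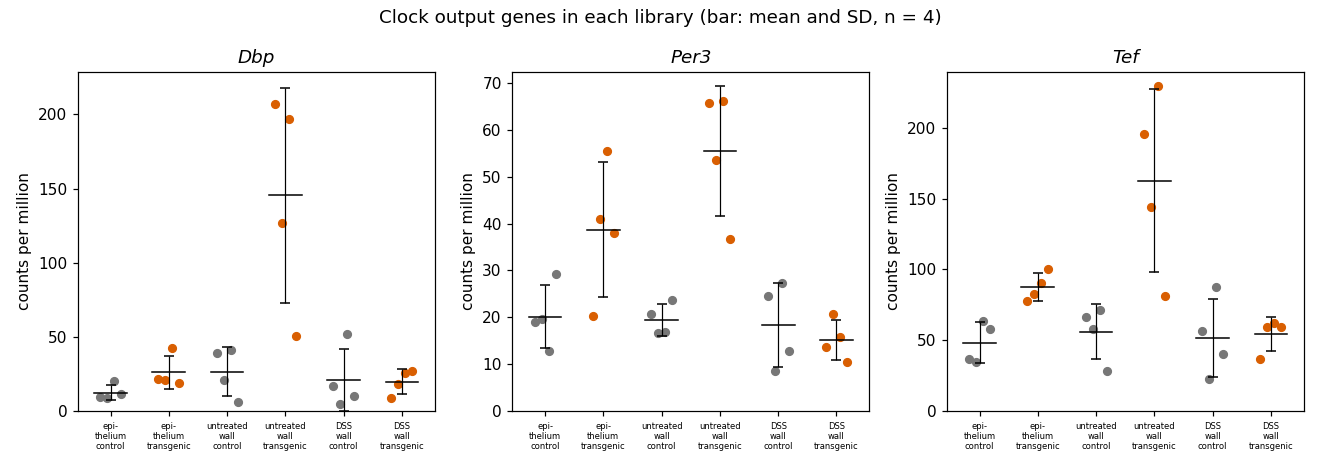
CPM (vertical axes) of the clock-controlled genes Dbp, Per3 and Tef in each library of the 6 groups (horizontal axes), with the mean and SD of 4 libraries as bars. Per3 was at 36.8 to 66.1 CPM in untreated transgenic wall and at 16.6 to 23.8 CPM in untreated control wall.

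In control colon wall, DSS raised genes of inflammation, interferon response, stroma and vessels, and lowered crypt and proliferation genes. These are shares of the RNA of whole wall. In either genotype, a change in the mix of cells and a change within cells therefore cannot be told apart. Slpi, a secreted protease inhibitor, rose by 4.37 ± 0.51 log2 units, from 8.58 ± 3.32 to 175.8 ± 119.6 CPM, and Nos2 rose by 3.59 ± 0.46. Lgr5, a marker of crypt stem cells (chromosome 10, 115450314 to 115587780), fell by 4.04 ± 0.31 from 7.61 ± 1.81 to 0.45 ± 0.1 CPM, and Ascl2, a stem cell transcription factor, fell by 5.58 ± 0.47. In edgeR's test, 6300 of 16074 genes passed, 3713 higher and 2587 lower, and 3148 of them changed by more than 1 log2 unit. Adjusted p was 7.18e-05 for Slpi, 0.000109 for Nos2, 1.2e-06 for Lgr5 and 3.37e-06 for Ascl2. Groups did not overlap for 33.3% of the genes, where chance gives 2.86%. Nfe2l2 itself was fitted 0.15 ± 0.19 higher with an adjusted p of 0.539. Without the second batch 6375 genes passed, and voom called 9501.

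Immune lists rose with DSS in control wall. All 14 neutrophil markers passed, with S100a9, a calcium-binding protein of neutrophils, at 0.43 ± 0.27 CPM untreated and 9.87 ± 5.22 CPM with DSS. Of 18 monocyte and macrophage markers 17 rose, among them Ccr2, a chemokine receptor, by 2.52 ± 0.43. Of 24 cytokines and chemokines 18 rose, among them the cytokine gene Tnf by 2.32 ± 0.34 and Il1b by 4.05 ± 0.92, with 112.9 CPM of Il1b in DSS replicate 4 and at most 18.9 CPM in the others. All 20 interferon-stimulated genes rose, among them Zbp1, a nucleic acid sensor, by 2.42 ± 0.33 and Ifit3 by 2.25 ± 0.36. Of 18 antimicrobial and host defence genes 10 rose, among them Duox2, an epithelial oxidase, by 1.91 ± 0.43, and Nox1, another epithelial oxidase, fell, though it was at 7.51 CPM in DSS replicate 1. Of 15 T cell markers 8 rose, among them Cd4 by 2.01 ± 0.44 and Foxp3, a marker of regulatory T cells, by 1.96 ± 0.50. No B and plasma cell marker and no MHC class II gene passed, of 13 and 10 tested. Fry called the 6 lists that rose higher (adjusted p from 0.00039 for interferon-stimulated genes to 0.0418 for T cells). Camera called them too and lost them with an estimated correlation: adjusted p = 0.301 for the neutrophil, interferon and antimicrobial lists, 0.421 for macrophages, 0.673 for cytokines and 0.709 for T cells.

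Stromal lists moved the same way in control wall. All 12 endothelial markers rose, among them Pecam1, an adhesion molecule, from 40.1 ± 5.13 to 113.7 ± 18.3 CPM, and Tek, an angiopoietin receptor, by 1.99 ± 0.21. All 18 fibroblast and collagen genes rose, among them Lum, a matrix proteoglycan, by 1.62 ± 0.18 and Fbln2, a fibulin, by 1.37 ± 0.19. Of 14 enteric neuron and glia markers 12 rose, among them Sox10, a transcription factor of glia, by 1.85 ± 0.31, with 14.99 CPM in DSS replicate 3 above the others. Of 18 matrix remodelling and repair genes 12 rose, among them Timp1, a protease inhibitor, by 2.81 ± 0.54 and Ly6a, a surface protein, by 2.21 ± 0.24. Mmp10, a matrix protease, rose by 5.76 ± 1.35, with 146.8 CPM in DSS replicate 4 and at most 10.4 CPM in the others. Without the second batch, which includes that library, Mmp10 no longer passed. Of 13 smooth muscle markers 6 rose, without a camera or fry call. All 8 red blood cell genes rose, Alas2, the erythroid enzyme of heme synthesis, to 93.5 ± 163 CPM, with 337.2 CPM in DSS replicate 3. Of 15 immediate early genes 8 rose, and of 9 adipocyte markers 1 rose. Fry's adjusted p was 1.27e-06 for the endothelial, 0.000139 for the fibroblast, 0.00706 for the neuronal and 0.0359 for the matrix list. Their camera calls were lost, with adjusted p = 0.0523, 0.248, 0.568 and 0.694 with an estimated correlation. The red cell list, called by camera, had adjusted p = 0.709 with an estimated correlation and 0.0587 in fry.

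Epithelial and metabolic lists mostly fell or split in control wall. All 20 proliferation genes fell, among them Mcm7, a replication helicase subunit, by 1.39 ± 0.19 and Pcna, a clamp for DNA polymerase, fell by 0.95 ± 0.13. Of 16 crypt stem and Wnt target genes 9 fell and 2 rose. Of 24 glutathione genes 12 fell, among them Gpx2, an epithelial glutathione peroxidase, by 2.07 ± 0.32. Of 14 quinone and thioredoxin genes 3 fell, among them Cbr3 by 2.62 ± 0.61 and Nqo1 by 1.38 ± 0.49. Of 37 drug metabolism genes 11 fell and 1 rose, and of 6 NADPH-producing enzymes 2 fell. Of 20 cholesterol and fatty acid synthesis genes 8 fell and 1 rose. Fry called the crypt (adjusted p = 0.000139), proliferation (0.00397), glutathione (0.0359) and cholesterol (0.0252) lists lower. Camera called these and the drug metabolism list lower, and lost them with adjusted p = 0.17, 0.39, 0.632, 0.568 and 0.713 with an estimated correlation.

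Other epithelial lists in control wall had no directional call. Of 16 tight junction genes 4 fell and 1 rose, among them Cldn2, a pore-forming claudin, from 232.7 ± 68.2 to 12.7 ± 19.5 CPM, with 334.2 CPM in untreated replicate 2 and 41.9 CPM in DSS replicate 1. Of 14 pan-epithelial markers 3 fell and 1 rose. Of 16 colonocyte markers 2 fell, among them Guca2b, a guanylate cyclase activator, by 1.95 ± 0.38, and 1 rose. Of 13 goblet cell markers 3 rose, among them Clca3, a mucus protein, by 0.91 ± 0.24, and 3 fell, among them the transcription factor Creb3l1, which fell by 1.28 ± 0.36. Of 13 enteroendocrine markers 5 rose, among them Gcg, which encodes glucagon and GLP-1, by 1.30 ± 0.42. The Gcg call was lost without the second batch and without control untreated replicate 1, 3 or 4 or DSS replicate 2. The Nqo1 call was lost without untreated replicate 1 or 2 or DSS replicate 2, 3 or 4. Of 18 fatty acid oxidation genes 5 fell, of 13 cornified envelope genes 3 rose and 2 fell, of 15 clock genes 1 rose and 1 fell, and of 15 unfolded protein response genes 1 fell.

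In transgenic colon wall, DSS raised genes of inflammation and stroma and lowered crypt and proliferation genes. Slpi rose by 4.43 ± 0.51 log2 units, from 8.58 ± 2.11 to 184.5 ± 70.2 CPM, and Nos2 by 3.62 ± 0.47. Lgr5 fell by 4.19 ± 0.31, from 8.92 ± 2.02 to 0.49 ± 0.18 CPM, and Ascl2 fell by 5.56 ± 0.45. Reg4, a secreted lectin of deep crypt cells, fell from 539.6 ± 180.6 to 36.1 ± 18.8 CPM, and Trpv6, a calcium channel, fell by 3.64 ± 0.72. In edgeR's test, 6626 of 16074 genes passed, 3710 higher and 2916 lower, 3245 of them by more than 1 log2 unit. Adjusted p was 5.15e-05 for Slpi, 8.26e-05 for Nos2, 6.41e-07 for Lgr5 and 1.83e-06 for Ascl2. Groups did not overlap for 35% of the genes. Nfe2l2 was fitted 0.12 ± 0.19 higher (adjusted p = 0.618), a sign that turned without DSS replicate 3 (-0.05) and in voom (-0.01). Without the second batch 6949 genes passed. These values include the library labelled untreated transgenic replicate 2.

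Immune lists rose with DSS in transgenic wall. Of 14 neutrophil markers 13 rose over all genes and 14 over the list alone, with S100a9 at 0.11 ± 0.05 CPM untreated and 9.77 ± 4.6 CPM with DSS. Of 24 cytokines and chemokines 21 rose, among them Tnf by 3.25 ± 0.36, and of 18 macrophage markers 16 rose. Of 20 interferon-stimulated genes 11 rose, among them Zbp1 by 2.27 ± 0.33, and of 18 antimicrobial genes 11 rose and 1 fell. Of 15 T cell markers 4 rose, of 13 B and plasma cell markers 1 fell, and of 10 MHC class II genes 0 passed. Fry called the first 5 lists higher (adjusted p = 0.000386 for neutrophils, 0.00603 for cytokines, 0.0171 for macrophages, 0.00725 for interferon and 0.000284 for antimicrobial genes). Their camera calls were lost, with adjusted p = 0.247, 0.543, 0.571, 0.543 and 0.24 with an estimated correlation.

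Among stromal lists in transgenic wall, all 12 endothelial markers (Eng, a coreceptor, by 1.55 ± 0.17), all 18 fibroblast genes (Fn1, fibronectin, by 1.61 ± 0.23) and all 14 neuron and glia markers (Nos1, neuronal nitric oxide synthase, by 2.20 ± 0.32) rose. Of 18 matrix remodelling genes 12 rose over all genes and 16 over the list alone, of 13 smooth muscle markers 7 rose, of 8 red blood cell genes 7, and of 15 immediate early genes 9 over all genes and 11 over the list alone. Of 9 adipocyte markers 1 rose over all genes, Plin4, a lipid droplet protein, by 1.34 ± 0.30, with 41.4 CPM in untreated replicate 3, and 7 over the list alone. Fry's adjusted p was 5.79e-06, 0.000284, 0.00603 and 0.00603 for the first 4 lists and 0.0419, 0.0127 and 0.0294 for the red cell, immediate early and adipocyte lists. Smooth muscle was called by camera alone. These 8 camera calls were lost, with adjusted p = 0.179, 0.24, 0.543, 0.543, 0.571, 0.571, 0.571 and 0.612 with an estimated correlation, smooth muscle last.

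Of epithelial lists in transgenic wall, 12 of 20 proliferation genes fell over all genes and 15 over the list alone, and of 16 crypt genes 8 fell and 2 rose. Of 16 tight junction genes 5 fell and 1 rose, of 18 fatty acid oxidation genes 7 fell, among them Pparg, a nuclear receptor, by 1.24 ± 0.28, and of 20 cholesterol genes 8 fell, among them Idi1, an isomerase of isoprenoid synthesis, which fell by 1.29 ± 0.26. Fry called these 5 lists lower (adjusted p = 0.00603, 0.000284, 0.0432, 0.0294 and 0.0343). Camera called all but the tight junction list, and lost them with adjusted p = 0.543, 0.24, 0.571 and 0.571 with an estimated correlation. Of 24 glutathione genes 6 fell over all genes and 2 over the list alone, of 37 drug metabolism genes 9 fell and 2 rose, and of 16 colonocyte markers 5 fell, among them Slc26a3, a chloride exchanger, by 1.01 ± 0.30, and 1 rose. Camera alone called these 3 lists lower, with adjusted p = 0.65, 0.612 and 0.571 with an estimated correlation. The Slc26a3 call was lost without untreated replicate 3. Of 14 quinone and thioredoxin genes 0 passed, with Nqo1 at 93.6 ± 48.9 CPM untreated and 74.6 ± 43.6 CPM with DSS, and of 6 NADPH enzymes 2 fell and 1 rose.

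Clock genes in transgenic wall went both ways: of 15, 3 rose and 5 fell, with Dbp down to 19.6 ± 8.45 CPM and Per3 to 15.1 ± 4.33 CPM (fitted changes -2.89 ± 0.70 and -1.88 ± 0.32, edgeR adjusted p = 0.0043 and 0.000433). Fry's mixed test gave an adjusted p of 0.00173 for this list, and 0.166 for it in control wall. Dbp and Per3 were higher in untreated transgenic than in untreated control wall, and sampling times are not given. A DSS effect on clock genes and a difference in sampling time therefore cannot be told apart. Of 13 goblet markers 2 rose and 1 fell, of 13 enteroendocrine markers 4 rose and 1 fell, of 14 pan-epithelial markers 1 fell, of 13 cornified envelope genes 2 rose and 1 fell, and of 15 unfolded protein response genes 3 rose, among them Hspa5, a chaperone of the endoplasmic reticulum, by 1.17 ± 0.28.

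**Figure D4:**
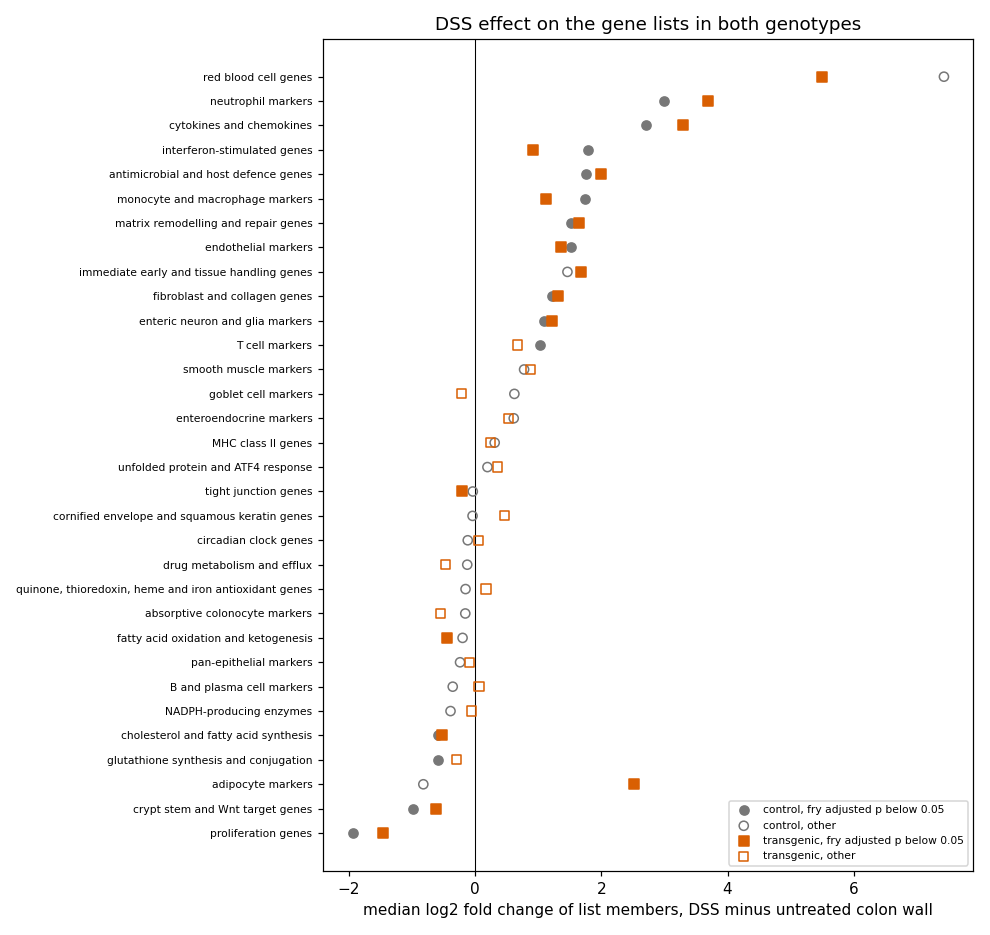
Median fitted log2 fold change with DSS over the members of each list (horizontal axis) for the 32 lists (vertical axis), in control (circles) and transgenic (squares) colon wall, filled where fry's adjusted p was below 0.05. Endothelial markers had medians of 1.52 and 1.36, and proliferation genes -1.94 and -1.47.

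The DSS calls of both genotypes were compared by overlap. Of the 3713 genes higher in controls and 3710 higher in transgenic wall, 2828 were shared, where independent lists would share 857 (Fisher's exact test, odds ratio 41.6, 95% interval 37.5 to 46.1). Of 2587 and 2916 lower genes, 1751 were shared, where 469 would be by independence (odds ratio 22.1, 20.0 to 24.6). Both p-values were below the smallest number the computer holds. The test takes genes as independent, which genes that change together are not, and both contrasts came from the same fit. These p-values and intervals therefore do not measure the spread between libraries. Only 8 genes were called in opposite directions. The compared groups have no library in common.

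With DSS, 15 genes passed edgeR's test between transgenic and control colon wall, all higher, 6 of them members of the glutathione, quinone and drug metabolism lists. Gclc rose by 3.13 ± 0.46 log2 units (adjusted p = 0.0238), from 66.1 ± 14.6 to 580.3 ± 221.2 CPM. Nqo1 rose by 3.16 ± 0.52 from 8.34 ± 2.37 to 74.6 ± 43.6 CPM, and Cbr3 by 3.91 ± 0.64 (both adjusted p = 0.0271). Abcc4 rose by 1.93 ± 0.33 and Adh7, an alcohol dehydrogenase, by 4.10 ± 0.65 (adjusted p = 0.0307 and 0.0271). Gsta1 rose by 3.93 ± 0.68 (adjusted p = 0.0332), and Gsta2 was at 0.056 ± 0.011 CPM in controls, with 1 to 3 counts per library, and at 13.6 ± 12.5 CPM in transgenic wall (adjusted p = 0.0435). The other 8 were Acox2, H60c, Il1f9, Serpinb11, Slc5a4b, Sprr2g and the predicted genes Gm10639 and Gm3776. Gsta1 and Gsta2 may share reads, and whether the predicted genes share reads with listed genes was not tested. The 15 calls may therefore not be independent. In this comparison 407 genes had an unadjusted p below 0.05, where chance alone gives 804, and values of 1.67% of the genes did not overlap, where chance gives 2.86%.

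Of the lists with DSS, all 24 glutathione genes were fitted higher in transgenic wall (median 0.996), 3 passing over all genes and 15 over the list alone. All 14 quinone and thioredoxin genes were fitted higher (median 0.79), 2 passing over all genes and 9 over the list alone. All 6 NADPH-producing enzymes were fitted higher (median 0.58), and 3 passed over the list alone, among them Taldo1, a transaldolase, at 363.7 ± 157 against 168.8 ± 3.52 CPM. Camera called these 3 lists, and kept them with an estimated correlation (adjusted p = 0.0125, 0.0131 and 0.0131), while fry gave adjusted p = 0.114 for each. Of 37 drug metabolism and efflux genes 1 passed over all genes and 12 over the list alone, all higher, with adjusted p = 0.0693 with an estimated correlation. All 9 adipocyte markers were fitted higher (median 2.24) with 0 past the threshold, and 18 of 20 interferon-stimulated genes were fitted lower (median -0.33), again with 0 past it. Camera called both, and lost them with adjusted p = 0.115 and 0.338 with an estimated correlation. Neutrophil, macrophage, T cell, cytokine and epithelial lists had no call, with 0 members past the threshold.

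The count of 15 with DSS was 3, 0, 0 and 1 without control DSS replicate 1, 2, 3 or 4, and 36, 7, 0 and 0 without transgenic DSS replicate 1, 2, 3 or 4. It was 0 among the 12 libraries of the first batch, 0 with the replicate block and 0 in voom, and 43 in DESeq2. Dbp was fitted at -0.07 ± 0.66, a sign that turned without control DSS replicate 3 (0.90).

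The DSS effect was then compared between genotypes. Cbr3 was lower with DSS in controls (46.4 ± 19.1 to 7.51 ± 0.97 CPM) and at 152.9 ± 87.1 and 113.6 ± 85.4 CPM in transgenic wall, a difference of effects of 2.19 ± 0.82 log2 units that did not pass (adjusted p = 0.521, edgeR). Gpx2 differed by 1.26 ± 0.43 and Ifit1, an interferon-induced gene, by -2.15 ± 0.62 (adjusted p = 0.478 and 0.445). Per3 differed by -1.78 ± 0.44, the only gene to pass over its list alone (adjusted p = 0.0127). Its values already differed between the untreated groups, and sampling times are not given. Nfe2l2 differed by -0.03 ± 0.27, and its sign turned with RLE scaling and in DESeq2 (0.02 in both) and without the second batch (0.12). The edgeR test called 0 genes, with 1279 at an unadjusted p below 0.05 where chance gives 804. DESeq2 called 40, voom 113, the first batch alone 98, and leaving out control untreated replicate 4 gave 93 and transgenic untreated replicate 4 gave 2.

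Camera called 8 lists in that difference. A more positive DSS effect in transgenic wall was fitted for the glutathione (median 0.32), quinone (0.37), cytokine (0.63), matrix (0.20), adipocyte (3.42) and immediate early (0.26) lists, and a more negative one for macrophage (-0.63) and interferon-stimulated genes (-0.43). All 8 had adjusted p = 0.747 with an estimated correlation, and fry gave adjusted p = 0.818 for each. Among the adipocyte markers, Lep, the gene of leptin, had 1.19 ± 2.29 CPM in untreated controls, of which 4.62 CPM stood in replicate 2 alone.

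The transgene effect was also compared between epithelial cells and untreated wall. The labels give a colon segment for the wall pieces only, so a difference between tissues and one between colon regions cannot be told apart here. Hlf, a clock-controlled transcription factor, differed by -3.96 ± 1.02 log2 units and Pdk4 by -2.15 ± 0.52 (adjusted p = 0.343 and 0.336, edgeR). Both passed over their lists alone (adjusted p = 0.0127 and 0.0131), as did Mx1 at -2.16 ± 0.60 (adjusted p = 0.0493). Gclc differed by -0.67 ± 0.67 and Nqo1 by -0.87 ± 0.70, with adjusted p = 0.853 and 0.811. The edgeR test called 0 of 15073 genes, with 1203 at an unadjusted p below 0.05 where chance gives 754. DESeq2 called 66 and voom 827, the fit without the second batch 5, and leaving out control wall replicate 4 gave 12, epithelial control replicate 3 gave 3 and epithelial transgenic replicate 1 gave 9. Camera called 1 list, immediate early and tissue handling genes (median 0.63), and lost it with adjusted p = 0.996 with an estimated correlation. Hspa1a, of that list, differed by 3.79 ± 1.14 (adjusted p = 0.435).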

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

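The tests of the explanations below were chosen after the results were seen, while the count over other splits of the libraries was planned. In 292 sets of 4 values, each a gene in a group, 31 values stood far from the others by Dixon's ratio. For independent, normally distributed values about 1 in 20, or 14.6, would do so. CPM values need not be normal and the sets share libraries, so no excess over chance is shown. Values are in CPM, with the nearest other library of the group in brackets where it is given.

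In control wall with DSS, replicate 1 was high for epithelial genes: Gsta3 12.5 (1.34), Cldn2 41.95 (3.07), Reg4 157.1 (22.8), Nox1 7.51 (0.41) and Sult1a1 160 (56.9). Replicate 4 was high for Il1b at 112.9 (18.9), Mmp10 at 146.8 (10.4) and Mmp3 at 175.1 (36.7). Replicate 3 was high for Alas2 at 337.2 (30.2) and stood apart for Sox10 at 14.99. In transgenic wall with DSS, replicate 1 stood apart for Mmp10 at 94.75 (12.7), Cxcl2 at 11.28 and Tef at 36.32, and replicate 2 for Ly6a at 1693. In untreated controls, replicate 2 stood apart for Cldn2 at 334.2 (207.6), Reg4 at 1854 (484.6) and Lep at 4.62, and replicate 4 for Tnf at 3.99. In untreated transgenic wall, replicate 4 stood apart for Mx1 at 3.64, Dapp1 at 21.53, Lum at 23.4, Alas2 at 0.819 and Cldn2 at 235.3. Replicate 1 stood apart there for S100a8 at 0 and Lep at 0.495, and replicate 3 for Plin4 at 41.37.

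In epithelial cells, control replicate 3 stood apart for Abcc4 at 11.14 (19.9) and Gsta1 at 54.35 (13.1). Transgenic replicate 1 stood apart for Gsta1 at 210.4 (56.7), replicate 3 for Dbp at 42.39 and replicate 4 for Ccna2 at 82.21.

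A difference between groups was found by camera for 9 lists and was lost for each with an estimated correlation (adjusted p = 0.747 for the first 8 and 0.996 for the last). The DSS effect differed between genotypes by a median of 0.318 for the glutathione list, 0.371 for quinone and thioredoxin genes, 0.626 for cytokines, -0.634 for macrophage markers, 0.201 for matrix remodelling, -0.428 for interferon-stimulated genes, 3.418 for adipocyte markers and 0.256 for immediate early genes. The transgene effect differed between tissues by 0.628 for immediate early genes.

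The library labelled untreated transgenic replicate 2 had a glutathione score of 6.13, below the highest control and against 6.97 or more in the other 3 transgenic libraries. Nqo1 and Gclc lay within the control range there, while Abcc2 at 6.21 CPM (controls up to 4.33) and Slc7a11 at 4.80 CPM (up to 4.44) lay just above it. A swap with a control library of this tissue would need a partner out of place, and 0 of the 4 control libraries reached the lowest of those transgenic scores. A lower share of epithelial cells is argued against by its pan-epithelial score, 0.123 above the other 3. No activity of the transgene, or a single wrong label, may explain it and stays open: Nfe2l2 was at 147.6 CPM, between the control range of 99.5 to 146.2 and the other transgenic range of 189.7 to 238.5. Epithelial transgenic replicate 4 shares its file-name number and may come from the same animal. Nfe2l2 in that epithelial library lay above all control epithelial libraries. Whether both came from the same animal is not given, so this decides nothing.

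Control 3 and transgenic 1 epithelial libraries stood apart from the other 6. Fewer cells from outside an unchanged epithelium is argued against, since the crypt score differed from the others by -1.19. More surface and less crypt epithelium may explain it, with a colonocyte score higher by 2.004, and so may different handling before lysis, with an immediate early score of -2.328 relative to the others. These 2 explanations stay open and do not exclude each other. The pattern appears in 1 library of each genotype, and a biological difference between these animals was not tested.

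Clock genes differed with genotype in untreated tissue. Tissue taken at different times of day in the 2 genotypes may explain this, as 10 of 13 clock genes had the same sign in epithelial cells and colon wall, and activity of the transgene would give that too. A clock index was taken as the mean log2(CPM + 1) of Dbp, Tef and Per3 less that of Arntl and Npas2. These genes were chosen after they were seen to differ between these groups, so the index is no independent test. The library labelled untreated transgenic replicate 2, with its glutathione score in the control range, had an index 90.7% of the way from the control mean to the other transgenic libraries. It was in the transgenic group when those differences were seen, and 1 library decides nothing. In DSS-treated wall, where Gclc and Nqo1 were higher in transgenic mice, the clock index did not separate the genotypes (-3.00 to 0.53 in controls, -1.46 to -0.55 in transgenic mice). The explanations cannot be told apart, because sampling times are not given in the sources used here. The DSS change of clock genes in transgenic wall and the Per3 difference of effects also rest on the untreated transgenic libraries. Their index was 0.498 to 3.035, against -2.122 to 0.022 in untreated controls.

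Other splits of the libraries were refitted for each comparison. For untreated wall by genotype, 1 of 35 splits gave at least 36 genes, the real one, and the highest other gave 4. That share is under 0.05 and the smallest that 35 splits can give, so it argues against chance for this count only. For DSS, 1 of 35 splits reached the real count in each genotype, with 6300 genes against at most 15 in controls and 6626 against at most 53 in transgenic wall. This argues against chance for these counts, with the same limit. The 20 splits that part the replicate 4 libraries, the second batch, as the real one does are too few for a share under 0.05, and their highest others were the same 4, 15 and 53. With a batch term, untreated wall had 19 genes. For genotype with DSS, 3 of 35 splits gave at least 15 genes and the highest other gave 361, so chance cannot be excluded. That split set control 2 and 4 with transgenic 1 and 2 against the rest. It was picked as the highest of the splits, and may point to a structure among the DSS libraries other than genotype, which was not tested. For the glutathione median chance cannot be excluded in any comparison of 2 groups: 7 of 35 splits reached it in epithelial cells (0.604, highest other 0.894), 3 in untreated wall (0.546, 0.626), 3 with DSS in controls (0.591, 0.642), 13 in transgenic wall (0.299, 0.748) and 2 by genotype with DSS (0.996, 1.005). Nor can it be for the genes at an unadjusted p below 0.05 in untreated wall (1681, highest other 1733, 3 of 35). For epithelial cells and both differences of effects the real count was 0, which 35 of 35 and 100 of 100 splits reach whatever the data, so these counts say nothing about chance. The highest other split gave 0, 418 (between genotypes) and 298 (between tissues) genes. By genes at an unadjusted p below 0.05, chance cannot be excluded: 10 of 35 splits reached 1344 in epithelial cells (highest other 3271), 17 of 100 reached 1279 between genotypes (3309) and 22 of 100 reached 1203 between tissues (3204).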

How the results depend on the processing

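The robust fit, the fit without 2 epithelial libraries and the term for the endothelial score were chosen after seeing the data. No scaling moved the median of all genes by over 0.1. The DSS counts stayed within 1.5 times their value, except in voom for controls (9501 genes for 6300) and for calls shared by both genotypes (7181 for 4579).

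Counts of genes past the threshold changed as follows, and the cause was not tested. In epithelial cells (0 genes), DESeq2 gave 215, voom 1292, the fit without control 3 and transgenic 1 835, the endothelial term 212, and leaving out 1 library 0 to 24 (without control 3). For untreated wall by genotype (36), DESeq2 gave 235, voom 2491, the replicate block 7, the batch term 19, the first batch alone 404, and only the 2 groups compared 10. Leaving out 1 library gave 5 (without control 3) to 320 (without control 4), and DESeq2 kept all 36 genes and voom 33. For genotype with DSS (15), DESeq2 gave 43 and kept all 15, while voom, the block and the first batch alone gave 0, and leaving out 1 library 0 to 36 (without transgenic 1). For the difference between genotypes (0), DESeq2 gave 40, voom 113, the first batch 98, and leaving out 1 library 0 to 93 (without untreated control 4). For the difference between tissues (0), DESeq2 gave 66, voom 827, the fit without the second batch 5, and leaving out 1 library 0 to 12 (without wall control 4). Without the 4 epithelial libraries that share a file-name number with a wall library, edgeR gave 0 there, with 806 genes at an unadjusted p below 0.05. That fit kept fewer epithelial libraries, control 3 and transgenic 1 among them, and the full fit already gave 0. It therefore cannot show whether shared animals matter.

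Among the named genes the sign reversed for 3 results, none of them past the threshold, and the cause was not tested. The Nfe2l2 difference of the DSS effect (-0.03) was 0.017 with RLE and in DESeq2, 0.119 in the first batch, and -0.204 to 0.137 leaving out 1 library. The Nfe2l2 change with DSS in transgenic wall (0.12) was -0.013 in voom and -0.051 to 0.225 leaving out 1 library. Dbp by genotype with DSS (-0.07) was 0.874 in voom, 0.45 with the block, 0.19 with the batch term, and -0.406 to 0.902 leaving out 1 library. Among genes named, leaving out 1 library gave the same call in 1318 tests, a lost call in 114, a gained call in 13 and a reversed sign in 11.

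Among all genes called with DSS, 1 reversed in controls in each of voom, the first batch alone and without DSS replicate 3 or 4, and 1 in transgenic wall without DSS replicate 2.

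With an estimated correlation camera kept 3 list calls, all for genotype with DSS. Fry kept 14 of 16 calls for DSS in controls and 16 of 20 in transgenic wall, and 0 elsewhere.

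Replicate numbers did not pair the libraries: correlations of same-numbered pairs ran from -0.558 to 0.281 in epithelial cells and from -0.168 to 0.182 in untreated wall. In simulated counts, 25.3% of genes changed 2-fold were recovered in the epithelial comparison, against 55.6% in untreated wall. The epithelial fit had lower depth, a larger coefficient of variation (0.36 against 0.26) and fewer libraries (8 against 16), and depth alone was not varied.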

Other observations

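Isx, an intestinal homeobox gene (chromosome 8, 74873174 to 74893506), rose with DSS by 6.81 ± 0.53 log2 units in control wall and by 6.00 ± 0.52 in transgenic wall (edgeR adjusted p = 1.43e-06 and 4.33e-06). It was at 0.19 ± 0.01 and 0.22 ± 0.13 CPM without DSS and at 22 ± 13.2 and 15.2 ± 8.29 CPM with it, in controls and transgenic mice. Lars2, a mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366940 to 123462664), fell by 4.55 ± 0.25 and by a fitted -4.17 ± 0.24 (adjusted p = 2.76e-08 and 8.11e-08). It was at 2162 ± 501.4 and 2229 ± 665.6 CPM without DSS and at 92.3 ± 12 and 123.6 ± 16.7 CPM with it. Whether all reads counted under Lars2 came from this gene was not tested, as the aligner and read filters are not given. A fall of this enzyme's own messenger RNA is therefore not shown. In transgenic wall Fam55b went from 129.5 ± 7.38 to 4.62 ± 1.91 CPM and Fut9, a fucosyltransferase, from 18.6 ± 2.47 to 1.17 ± 0.29 CPM.

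Hoxb8, a homeobox gene, was at 26.1 ± 7.82 CPM in control and 38.3 ± 9.1 CPM in transgenic epithelial cells and at 0.62 ± 0.34 and 0.53 ± 0.12 CPM in untreated control and transgenic wall, with 1.19 ± 0.48 and 1.46 ± 0.41 CPM after DSS. Hoxb13 was at 47.5 ± 18.1 and 41.9 ± 7.6 CPM in epithelial cells and at 473.3 ± 79.3 and 436.8 ± 98.2 CPM in untreated control and transgenic wall, with 298.7 ± 35.9 and 366.5 ± 168.8 CPM after DSS. Rn45s, the ribosomal RNA precursor, was at 3256 ± 2241 CPM in control and 14240.0 ± 18480.0 CPM in transgenic epithelial cells. Control replicate 3 was at 6608 and the other 3 at 2076, 1969 and 2372 CPM. Transgenic replicate 1 was at 41810.0 and the other 3 at 2429, 7154 and 5559 CPM. Control 3 and transgenic 1, which stood apart by marker lists, thus had the highest value of their groups, and the cause was not tested. In untreated control and transgenic wall Rn45s was at 2766 ± 1588 and 1261 ± 222.8 CPM, with 807.1 ± 189.9 and 945.2 ± 213 CPM after DSS.

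In epithelial transgenic replicate 3, 44 genes had a count of exactly 0 while every other epithelial library had over 2 CPM. The other epithelial libraries had 0 or 1 such gene. Chac1, of the unfolded protein list, is among the 44. Whether these zeros are measured or missing values is not given in the sources used here, and they entered the epithelial tests as 0.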
